A study of Mus musculus with 107 samples.

How the data were processed

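The series compares mice carrying a mutant Uromodulin gene (labelled HE) with wild type littermates in RNA sequencing libraries. Whole kidney and cells positive for uromodulin (Umod+ cells) were profiled at 4 ages, 6, 12, 24 and 30 weeks. Each library came from 1 mouse, so a library is 1 biological replicate, and different mice were killed at each age. The 107 libraries fell into 16 groups, 55 from whole kidney and 52 from Umod+ cells. In whole kidney there were 8 mutant and 7 wild type mice at 6 weeks, 7 and 8 at 12 weeks, 8 and 11 at 24 weeks, and 3 and 3 at 30 weeks. In Umod+ cells there were 8 and 8, 5 and 8, 9 and 9, and 2 and 3. Of the mice, 33 gave a library in each table: 15 at 6 weeks, 12 at 12 weeks, 1 at 24 weeks and 5 at 30 weeks. Sex, batch and time of collection, the way the Umod+ cells were isolated and the nature of the mutation are not given in the sources used here.

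The values are FPKM as deposited by the authors, with 1 file per tissue. Total RNA from C57BL/6 J mice was prepared with an RNeasy Plus Mini kit and sequenced from TruSeq Stranded mRNA libraries, per the labels' protocols. Reads were handled with Bowtie2 2.2.2, TopHat2 2.0.11 and Cufflinks 2.2.1 on genome build GRCm38, per the submitters' processing notes, which list these tools without stating the step each was used for. The tables hold no read counts, so the depth of each library is unknown and no count-based test could be run. Precision was therefore taken from the spread between mice. The FPKM of a library summed to between 712224 and 2011297 in whole kidney and between 888090 and 2727234 in Umod+ cells. Between 12914 and 14427 named genes reached 1 FPKM in a kidney library, and between 12145 and 13439 in a cell library.

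Whole kidney has 45889 loci and Umod+ cells 40939. Of these, 8574 and 3708 carry no gene name. Loci naming several genes (975 and 859) were kept as 1 locus under their joint name. In 23 kidney loci and 29 cell loci the FPKM estimate was taken to have failed in part of the libraries. Such a locus read 0 in some libraries, and in the others either had a median of at least 1000 FPKM or, with at least 500 exonic bases listed for its symbol, never fell below 5. For some loci named after clones, the length listed for the symbol exceeds the locus itself. Those loci were left out of all tests. They include Kap and Gpx3 in whole kidney and the locus joining Gp2 and Umod in Umod+ cells. Every sample name matched a column, with 0 columns left over. Exonic lengths and gene types came from GENCODE mouse release M21, and the coordinates given are those of the deposited loci on GRCm38.

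Values were analysed as log2(FPKM+1) after keeping named genes with at least 1 FPKM in at least 3 libraries, which left 16349 genes in whole kidney and 14775 in Umod+ cells. The added 1 FPKM understates the fold change of genes with low values, and every log2 difference in the text is on this scale. No further scaling was applied in the main analysis. Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, an intensity trend in the variance and all 8 groups of a table in the same model. The 6 comparisons per table were mutant minus wild type at each age, the change of that difference between 6 and 24 weeks (the interaction), and wild type at 24 weeks minus wild type at 6 weeks (ageing). Tests were two-sided and p-values were adjusted with the Benjamini-Hochberg method across the genes of a comparison. A gene is said to rise, fall or change where its adjusted p was below 0.05. Exact permutation tests were added for Umod. Tables were read with data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the figures were drawn with matplotlib 3.10.9. Each stated mean and standard deviation (SD) is in FPKM.

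For each gene group, 34 fixed lists of mouse genes were written from general knowledge before the data were examined. They cover cell types of the kidney and its surroundings, stress, death and injury programmes, immune signals and metabolism. The adrenal gland list could not be tested in either table, since Star was the only 1 of its 7 members to pass the filter, and the adipose list could not be tested in Umod+ cells. That left 33 and 32 lists. Each list was compared with all other genes by the limma function camera, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, and by fry, which tests whether a list's genes move 1 way on balance and makes no comparison with other genes. List p-values were adjusted across the lists of a comparison. For each list the text also gives members passing when the adjustment ran over the list alone. A list's median is the median log2 difference of its members.

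Genes named in the text follow a rule fixed before the data were examined. It names Umod at every age, and among changed genes whose higher group mean was at least 2 FPKM it takes those with the largest log2 difference. Up to 12 higher and 12 lower genes are named at 24 weeks, 6 and 6 at the other ages, and 5 and 5 for the interaction and for ageing. Predicted genes and symbols shared by several loci were counted and not named. The rule adds up to 4 members of each list, those with the smallest p at 24 weeks. A few genes that the rule gives are not reported here. Genes outside it are marked as chosen after their values were seen. Some genes given by the rule lost their call without any of several single libraries and are not described further: Kcnt1 in kidney at 12 weeks, Lhx1 in cells at 6 weeks, and for ageing Apob, Manf and C1qtnf6 in kidney and Napsa, Eci3, Mep1a and Pter in cells.

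Shared calls between tissues and between ages were compared with the number expected from independent lists, n1 × n2 / N over the genes tested in both. The whole procedure was tested on simulated data in which 200 genes were changed, 67 of them by a log2 change of 1 and 67 by 0.5. At a log2 change of 1 it recovered 73.1%, 85.1% and 56.7% of the 67 in kidney groups built like those at 6, 24 and 30 weeks, and 94.0%, 94.0% and 64.2% in cell groups. Between 3.7% and 9.2% of the calls were false. At a log2 change of 0.5 the kidney recovery was 31.3%, 43.3% and 14.9%. These rates hold for the simulated data only. Group labels were also redistributed among mice, up to 100 times per comparison, to see how many genes other splits of the same libraries would call.

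The alternatives tried were log2(FPKM+0.1), no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, fitting only the groups compared, limma's array weights, a fold change of at least 1.5, a sex covariate (Xist minus the mean of Ddx3y, Eif2s3y, Kdm5d and Uty), leaving out each library in turn, a proximal tubule covariate in Umod+ cells and an adjusted p below 0.1 for overlaps. These were fixed before the data were examined. A covariate for the level of long against short genes, keeping the failed loci, keeping only protein-coding loci with 1 gene, leaving out the 30-week libraries, leaving out kidney libraries with low long-gene levels, a macrophage covariate in Umod+ cells and the use of 24-week in place of 30-week wild type kidneys were added after the data had been seen. The long-minus-short value of a library is the median log2 deviation of its longest well expressed genes (at least 6778 exonic bases in kidney and 6662 in cells) minus that of its shortest (at most 2719 and 2704).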

Results

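The libraries were first compared for sex, long against short genes and unnamed loci. Xist, transcribed from the inactive X of females, was set against Y-linked genes. In kidney each group up to 24 weeks was near sex balance. At 24 weeks there were 4 female and 4 male mutants, and 6 and 5 wild types. All mice at 30 weeks were male by these genes. Umod+ cells at 24 weeks came from 6 female and 3 male mutants and 3 female and 6 male wild types. The long-minus-short value had a median of -0.81 (-1.21 to -0.66) in the 3 wild type kidneys at 30 weeks. It was 0.21 (0.10 to 0.23) in the 3 mutants of that age and 0.29 in each kidney group at 24 weeks. All kidney values below -0.5 were from males. Wild type males had -1.08 to -0.24 at 12 weeks and -0.52 to 0.29 at 24. Wild type Umod+ cells at 30 weeks had a median of -0.42 and mutant cells -0.06. Loci without a gene name took 10.4% to 48.5% of a kidney library and 19.4% to 70.7% of a cell library.

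**Figure D1:**
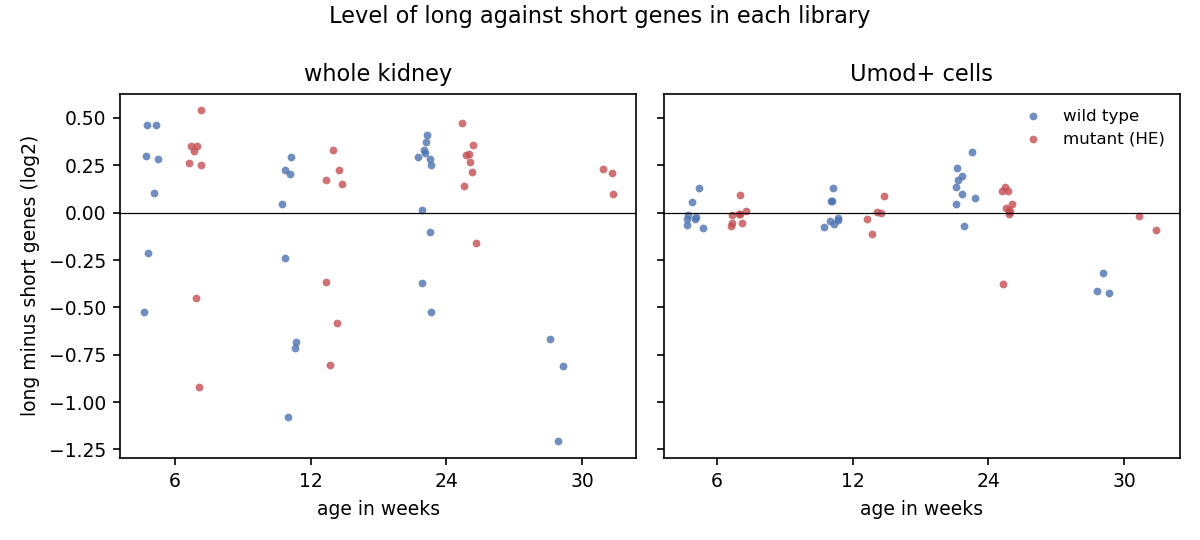
Long-minus-short value (log2, vertical axis) of each library by age in weeks, in whole kidney and in Umod+ cells, with wild type and mutant mice in separate colours. The wild type kidneys of 30 weeks lie below all mutant kidneys of that age.

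Umod encodes uromodulin, the protein of the thick ascending limb that carries the mutation in this model, and its level (chromosome 7, 119462436 to 119479347) was taken first in every group. In whole kidney it did not differ at 6 weeks (2743 ± 690 FPKM in 8 mutants, 2589 ± 265 in 7 wild types, log2 difference 0.05, exact permutation p = 0.726) or at 12 weeks (2513 ± 546 in 7 against 2508 ± 319 in 8, -0.01, exact p = 0.936). At 24 weeks it fell to 1623 ± 218 in 8 mutants against 2277 ± 334 in 11 wild types (log2 difference -0.49, adjusted p = 0.000493, exact p = 2.65e-05), below the wild type mean in 8 of 8 mutants, and under quantile normalization the difference was 0.05. At 30 weeks it was 1141 ± 182 in 3 mutants against 3405 ± 803 in 3 wild types (-1.56, adjusted p = 2.08e-08), and under quantile normalization -0.23. The exact p was 0.1, the smallest that 3 against 3 allow. From 6 to 24 weeks the difference changed by -0.54 (adjusted p = 0.0169; -0.03 under that scaling), and wild types did not change (-0.19, adjusted p = 0.914). They were higher at 30 weeks (3405). In Umod+ cells the gene has no locus of its own, and its joint locus with Gp2 reads 0 in 40 of 52 libraries. The locus was above 0 in 1 of 5 mutants at 12 weeks (13169), 8 of 9 at 24 weeks (10005 to 14404), 2 of 2 at 30 weeks (7233 and 7294) and 1 of 9 wild types at 24 weeks (20461), so Umod was not tested there.

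**Figure D2:**
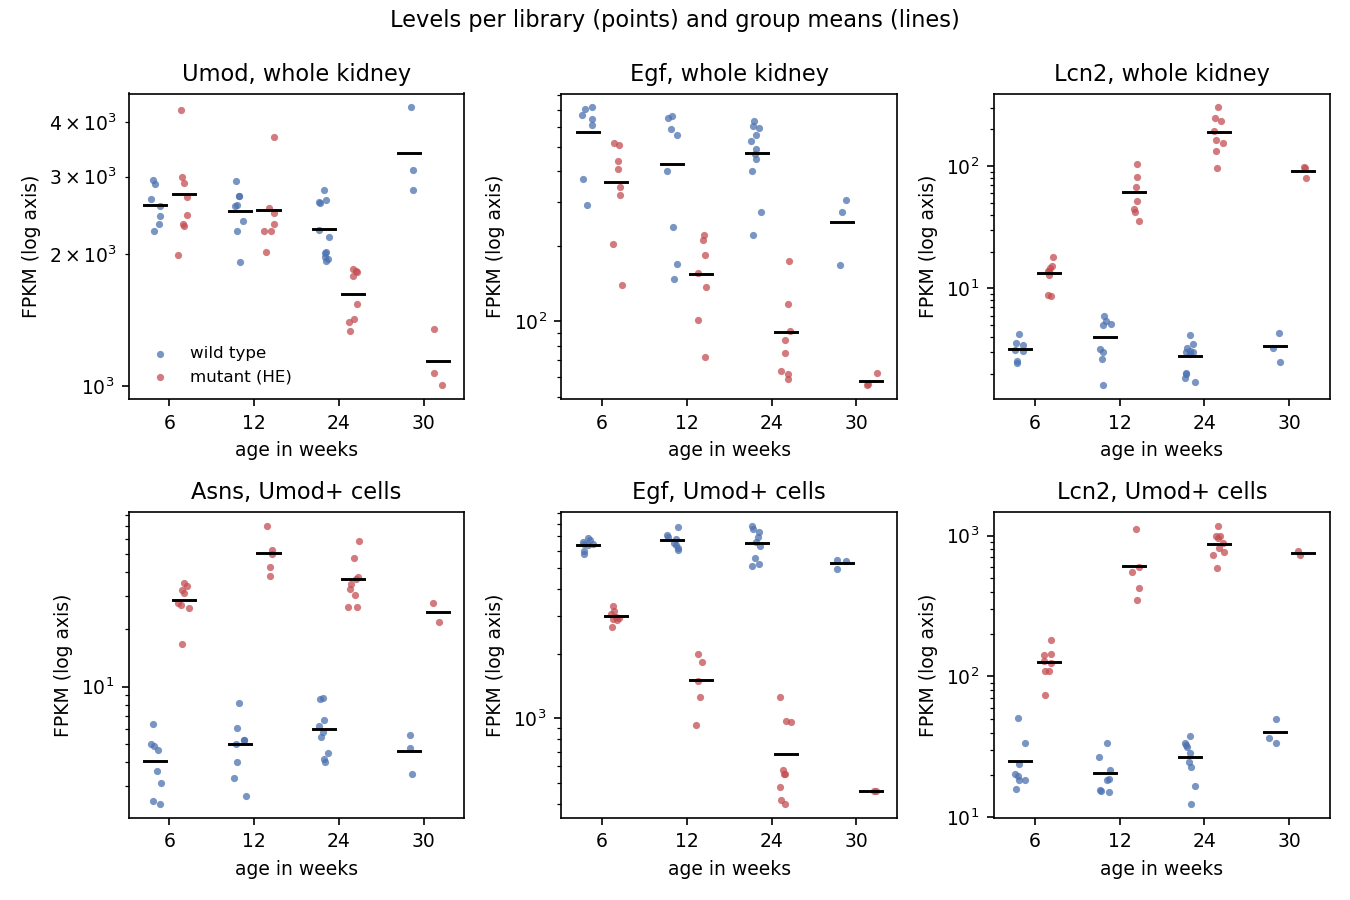
FPKM (vertical axis, log scale) of Umod, Egf and Lcn2 in whole kidney and of Asns, Egf and Lcn2 in Umod+ cells at each age in weeks; points are libraries of mutant and wild type mice, and lines are group means. Umod is lower in mutant kidneys at 24 and 30 weeks as deposited, and at 24 weeks this direction flips under quantile normalization (0.05).

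The comparison at 6 weeks asks which kidney genes differ at the youngest age. Lcn2 (chromosome 2, 32384632 to 32387797), an iron-carrier binding protein shed by injured tubules, rose to 13.3 ± 3.18 FPKM in 8 mutants from 3.22 ± 0.622 in 7 wild types (log2 difference 1.74, adjusted p = 6.98e-07, 8 of 8 mutants above the wild type mean). The matrix gene Smoc2 rose from 7.58 ± 2.02 to 28.0 ± 7.08 (1.76, adjusted p = 2.51e-06), and the protease inhibitor Timp1 from 1.15 ± 0.523 to 6.72 ± 3.72 (1.74, adjusted p = 0.00085). Serpina10 (1.33, adjusted p = 0.000388) and the calcification inhibitor Mgp (498 ± 222 against 195 ± 36.4, 1.26, adjusted p = 0.00588) rose as well, each in 8 of 8 mutants. The phosphatase gene Ptpn6 fell (34.6 ± 5.79 against 56.1 ± 12.0, -0.67, adjusted p = 0.0142), and this was lost without wild type replicate 4 (-0.60, adjusted p = 0.0656) or 3 (-0.62, adjusted p = 0.0597).

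Of 33 lists, 11 differed from other genes in kidneys at 6 weeks by camera, and 6 of these held with an estimated correlation. Tubular injury genes had a median of 0.36 (adjusted p = 8.93e-16), with 1 of 26 members higher over all genes and 11 higher and 1 lower when adjusted over the list alone. Complement genes had a median of 0.40 (adjusted p = 6.12e-14), and 2 of 10 rose, among them the inhibitor gene Serping1 (1.07), with 5 when adjusted over the list alone. Chemokine and cytokine genes had a median of 0.35 (adjusted p = 4.35e-12), and 3 of 22 rose, including Cxcl10 (1.00), with 6 when adjusted over the list alone. In the integrated stress response, which the factor ATF4 drives, 5 of 34 genes rose, including Atf5 (0.80), and the list had a median of 0.08 and a mean of 0.20 (adjusted p = 2.37e-06; 7 when adjusted over the list alone). The p53 list (0.16, adjusted p = 8.55e-06, 0 of 13 changed) and the fibroblast list (0.27, adjusted p = 1.53e-07, 2 of 12 higher) completed the 6.

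Extracellular matrix genes had the lowest p of the kidney lists at 6 weeks with the preset correlation (median 0.43, adjusted p = 6.72e-17). It became adjusted p = 0.0643 with an estimated correlation. Of its 32 members 2 rose, and 10 when adjusted over the list alone. Macrophage genes (0.33) went from adjusted p = 2.31e-11 to adjusted p = 0.0643 with an estimated correlation. Lymphocytes, endoplasmic reticulum chaperones and the proximal tubule made up the 11 and did not hold (adjusted p = 0.376, 0.227 and 0.384 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, did not pass (377 against 269 FPKM, 0.50). No gene of the thick ascending limb list changed (median -0.05, adjusted p = 0.508). The distal convoluted tubule list had a median of -0.01 but a mean of 0.06 (adjusted p = 0.417).

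Across all kidney genes at 6 weeks, limma called 57 of 16349, 50 higher and 7 lower, while 980 had an unadjusted p below 0.05. Higher genes were 87.7% of the calls, but 38.6% of the 840 called with array weights. Leaving out wild type replicate 3 gave 37 genes and 0 lower ones. Lower genes dropped to 2 without wild type replicate 6 and to 4 without replicate 5 or 4.

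At 12 weeks the same comparison asks what is added in kidneys in which Umod has not passed. Havcr1, a receptor that injured proximal tubules display, rose to 58.7 ± 49.8 FPKM in 7 mutants from 3.58 ± 5.01 in 8 wild types (3.83, adjusted p = 2.25e-08), above the wild type mean in 7 of 7. Lcn2 rose to 61.0 ± 24.9 from 3.99 ± 1.56 (3.61, adjusted p = 1.35e-18) and Timp1 to 19.4 ± 7.48 from 2.04 ± 1.97 (2.87, adjusted p = 1.06e-09). Serpina10 (16.6 ± 7.12 against 1.54 ± 0.511, 2.71), Smoc2 (48.7 ± 18.1 against 8.22 ± 2.19, 2.39) and the small GTPase regulator Arhgap36 (5.34 ± 4.06 against 0.122 ± 0.222, 2.27) rose in 7 of 7 mutants. Egf, the growth factor made by distal tubules, fell from 427 ± 217 to 155 ± 55.8 (-1.34, adjusted p = 0.00278; chromosome 3, 129675931 to 129755322), and under quantile normalization it missed the threshold (-1.18). Nccrp1 (8.94 ± 3.63 against 22.9 ± 4.84, -1.33, adjusted p = 0.0044), Tmem207 (-1.08, adjusted p = 4.96e-05) and the secreted protease inhibitor Wfdc15b (-1.03, adjusted p = 0.00186) fell too. The demethylase Kdm4b (-1.32, adjusted p = 0.0142) fell, but not without wild type replicate 6 (-1.09, adjusted p = 0.0581).

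By list, 20 of 33 differed in kidneys at 12 weeks and 9 held with an estimated correlation. Macrophage genes had a median of 1.00 (adjusted p = 2.91e-34) and 20 of 22 rose, and all 22 rose when adjusted over the list alone. Lymphocyte genes rose in 7 of 18 members (0.47, adjusted p = 3.11e-10; 12 when adjusted over the list alone). Extracellular matrix genes rose in 22 of 32 (0.99, adjusted p = 1.03e-37), tubular injury genes in 15 of 26 (0.55, adjusted p = 1.03e-28), chemokine genes in 13 of 22 (0.89, adjusted p = 6.41e-24) and complement genes in 9 of 10 (0.78, adjusted p = 2.36e-15). The integrated stress response rose in 13 of 34 members, including Atf5 (1.96) and Nupr1 (1.15), with a median of 0.25 (adjusted p = 5.02e-15). NF-kB targets (0.43, 9 of 15, adjusted p = 6.83e-12) and p53 targets (0.35, 4 of 13, adjusted p = 5.66e-06) were the last of the 9.

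The other 11 lists lost their call in kidneys of 12 weeks. The list of the thick ascending limb had 2 lower of 26 (median -0.17, adjusted p = 0.00675, and adjusted p = 0.206 with an estimated correlation). Proximal tubule genes had 1 lower (-0.32, adjusted p = 0.00101 and 0.180 with an estimated correlation). In all, limma called 848 genes (699 higher, 149 lower; 2383 at an unadjusted p below 0.05). Higher genes were 82.4% of these, but 57.6% of the 1754 called with the sex covariate. Lower genes dropped to 63 without mutant replicate 2 and to 99 without wild type replicate 5.

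The 24-week comparison asks how the kidney differs at the age when Umod is lower as deposited. Lcn2 reached 190 ± 67.2 FPKM in 8 mutants against 2.79 ± 0.784 in 11 wild types (5.60, adjusted p = 2.42e-29), the largest difference of any named gene. Havcr1 rose to 63.5 ± 31.4 from 2.58 ± 1.77 (4.17, adjusted p = 3.73e-12), the matrix protease Mmp7 to 15.0 ± 8.28 from 0.1 ± 0.155 (3.69, adjusted p = 1.48e-19) and Smoc2 to 90.5 ± 23.8 from 6.58 ± 2.31 (3.63, adjusted p = 6.28e-20). Igfbp2, which binds insulin-like growth factors, rose to 27.2 ± 12.9 from 1.15 ± 0.997 (3.69), and the acute phase gene Serpina3n to 20.6 ± 9.93 from 0.564 ± 0.490 (3.67). Myeloid genes followed, with the lysozyme Lyz2 at 299.5 ± 78.5 against 28.4 ± 12.8 (3.41) and the chemokine Ccl8 at 23.7 ± 12.7 against 1.4 ± 0.898 (3.31, adjusted p = 1.13e-12). Complement C3 rose to 260.2 ± 91.4 from 29.96 ± 19.2 (3.29). Each was above the wild type mean in 8 of 8 mutants.

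Some genes that rose in mutant kidneys at 24 weeks belong to other cell types and varied widely. The antibody genes Ighv6-3 (40.2 ± 47.0 against 3.13 ± 7.64, 3.50) and Igkv5-39 (56.6 ± 85.2 against 2.54 ± 4.03, 3.31) are made by plasma cells, and Ighv6-3 lay above every wild type in 3 of 8 mutants. Cfd, a product of fat cells, rose to 83.5 ± 123 from 3.05 ± 5.24 (3.64, adjusted p = 4.73e-05), above every wild type in 5 of 8. With it rose the fat genes Cidec (2.25), Adipoq (1.99) and Retn (1.81), 6 of 7 members of the adipose list (median 1.81, adjusted p = 0.013, and adjusted p = 0.363 with an estimated correlation).

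Among the genes with the largest falls in the kidney at 24 weeks, Egf fell to 90.6 ± 38.7 from 473 ± 133 (-2.40, adjusted p = 3.15e-10, 8 of 8 mutants) and the nuclease Dnase1 to 262 ± 169 from 1150 ± 375 (-2.32, adjusted p = 1.53e-09). The enzyme genes of amino acid metabolism that the rule names also fell: Gatm (298 ± 188 against 1035 ± 246, -1.97, adjusted p = 7.97e-12) and Hpd (60.9 ± 65.2 against 239.6 ± 139, -2.29, adjusted p = 7.78e-05, 7 of 8 mutants). The transporter Slc22a22 (25.7 against 98.1, -1.87), Wfdc15b (150 ± 49.7 against 542 ± 195, -1.82), Wfdc16 (-1.82), Sectm1b (-1.82), Fam151a (-1.80) and the liver-type glycogen synthase Gys2 (-1.77) fell as well. The methyltransferase Inmt passed narrowly (396 ± 431 against 1508 ± 1660, -1.90, adjusted p = 0.0463, 7 of 8). It was lost without mutant replicates 5 (-1.66), 6 (-1.69), 1 (-1.58) or 3 (-1.83), or without wild type replicates 4 (-1.83), 5 (-1.78), 1 (-1.74), 3 (-1.64) or 2 (-1.68), nor under quantile normalization (-1.53).

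Of the 33 lists, 23 differed in the kidney at 24 weeks, and 8 held with an estimated correlation. Extracellular matrix genes rose in 32 of 32 members (median 1.81, adjusted p = 3.87e-22), among them the collagen crosslinker Lox (13.1 against 1.04 FPKM, 2.68) and the proteases Mmp2 (20.3 ± 5.96 against 2.17 ± 0.655, 2.73) and Mmp14 (2.55). Macrophage genes rose in 22 of 22 (1.91, adjusted p = 3.87e-22), as with the cathepsin Ctss (116 ± 29.4 against 22.1 ± 5.05, 2.32), Mrc1 (11.6 ± 2.83 against 1.44 ± 0.507, 2.36), C1qc (77.3 ± 21.2 against 13.8 ± 3.04, 2.38) and Emr1 (1.99). Lymphocyte genes rose in 17 of 18 (1.06, adjusted p = 3.84e-11), including the receptor genes Il2rb (1.27) and Cd3e (1.08). Tubular injury genes rose in 23 of 26 (1.38, adjusted p = 1.37e-18), with the adhesion gene Vcam1 at 36.3 ± 8.10 against 6.60 ± 1.79 (2.31), Cd44 (2.00) and Sox9 (0.88).

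Chemokine and cytokine genes rose in 18 of 22 at this age (1.14, adjusted p = 1.73e-10), for example Cx3cl1 (62.9 ± 9.50 against 26.3 ± 6.81, 1.25) and Cxcl10 (1.4). NF-kB targets rose in 14 of 15 with 1 lower (1.12, adjusted p = 2.83e-09), including Relb (7.22 ± 1.73 against 1.85 ± 0.379, 1.51) and Icam1 (1.18). Complement rose in 9 of 10 (1.71, adjusted p = 3.77e-10), with Serping1 at 223 ± 35.4 against 43.9 ± 13.8 (2.36), C3ar1 (1.83) and C4b (14.9 against 2.01, 2.41). Proximal tubule genes fell in 16 of 24 (-0.91, adjusted p = 1.67e-08; 17 when adjusted over the list alone). Among them were the lactate transporter Slc5a12 (97.1 ± 28.7 against 262 ± 71.0, -1.43, adjusted p = 3.56e-12), the glucose producer G6pc (124 ± 54.9 against 309.6 ± 53.7, -1.41) and Miox (1545 ± 853 against 3712 ± 665, -1.39).

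In the thick ascending limb list, 9 of 26 genes fell and 2 rose in the kidney at 24 weeks (median -0.27, adjusted p = 0.0113, and adjusted p = 0.201 with an estimated correlation). Tmem207 (5.23 ± 2.06 against 14.5 ± 5.70, -1.29, adjusted p = 7.39e-09) fell, while the claudin Cldn19 rose (24.5 against 13.1, 0.90). The sodium pump subunit Atp1b1 fell (905 ± 100 against 1289 ± 130, -0.51, adjusted p = 1.66e-08) but not under quantile normalization, where the list median was -0.02. Endoplasmic reticulum chaperones fell in 16 of 25 (-0.43, adjusted p = 1.78e-05 and 0.147 with an estimated correlation). Hspa5 was at 222 ± 48.7 against 453 ± 111 (-1.01, adjusted p = 3.99e-05), Dnajc3 at -0.56 and Pdia3 at 288 ± 47.7 against 459 ± 48.2 (-0.68; -0.26 and no longer passing under quantile normalization). The degradation genes of that organelle fell in 5 of 18 (-0.15, adjusted p = 0.0314 and 0.147 with an estimated correlation), as with Herpud1 (174 ± 32.2 against 325 ± 40.1, -0.91).

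The integrated stress response rose in 19 and fell in 5 of 34 genes in kidneys at 24 weeks (0.53, adjusted p = 0.00211 and 0.0727 with an estimated correlation). Atf5 (23.8 ± 4.96 against 5.50 ± 1.22, 1.93), Nupr1 (58.2 ± 11.6 against 12.5 ± 3.35, 2.15) and Trib3 (6.79 against 0.786, 2.11) rose, and the cysteine enzyme Cth fell (107 ± 18.1 against 216 ± 34.7, -1.01). Apoptosis genes rose in 12 and fell in 4 of 26 (0.26, adjusted p = 0.0209 and 0.0736 with an estimated correlation), with higher Casp4 (1.77). Targets of p53 rose in 8 and fell in 1 of 13 (0.40, adjusted p = 0.00258 and 0.0518 with an estimated correlation; 9 higher and 2 lower when adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 21.7 ± 3.95 against 4.26 ± 0.650 (2.10). Proliferation genes rose in 17 and fell in 1 of 21 (0.61, adjusted p = 1.55e-05 and 0.147 with an estimated correlation). The interferon response rose in 18 of 22 (0.67, adjusted p = 1.53e-05 and 0.147 with an estimated correlation).

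Oxidative phosphorylation fell in 19 of 20 genes in mutant kidneys of 24 weeks (-0.81, adjusted p = 2.29e-09 and 0.147 with an estimated correlation), for example Ndufs1 of the respiratory chain (94.7 ± 21.5 against 188 ± 33.9, -0.99). Fatty acid oxidation fell in 9 of 17 (-0.45, adjusted p = 0.005 and 0.201 with an estimated correlation), with Acadm (393 ± 105 against 676 ± 90.8, -0.81) and its regulator Ppara (-0.90). Cholesterol synthesis fell in 11 of 17 (-0.62, adjusted p = 2.98e-05 and 0.102 with an estimated correlation), including Cyp51 (69.7 ± 21.3 against 158 ± 44.2, -1.18) and Hmgcs1 (-0.70). Proteasome genes fell in 11 of 24 (-0.39, adjusted p = 0.00146 and 0.515 with an estimated correlation; 13 when adjusted over the list alone). Immediate early genes rose in 5 and fell in 1 of 17 (0.55, adjusted p = 0.0273 and 0.495 with an estimated correlation), led by Myc (9.92 ± 2.25 against 2.11 ± 0.826, 1.82). Fibroblast genes rose in 6 and fell in 1 of 12 (0.53, adjusted p = 0.00451 and 0.147 with an estimated correlation), with Dcn at 165 ± 21.3 against 35.4 ± 11.9 (2.26), Pdgfra at 28.1 ± 7.94 against 7.46 ± 2.35 (1.79) and Lum (2.14).

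The remaining 10 lists did not differ from other genes in kidneys at 24 weeks, although single members changed. Distal convoluted tubule genes had 1 higher and 3 lower of 9 (-0.50, adjusted p = 0.0848), including the antiageing factor Kl (96.4 ± 32.3 against 206 ± 35.0, -1.14). Principal cells had 4 higher and 1 lower of 10 (0.31, adjusted p = 0.179), with the water channel Aqp2 higher (234 ± 155 against 54.9 ± 38.2, 1.89) and Aqp4 lower (8.54 against 21.3, -1.16). Intercalated cells had 1 higher and 5 lower of 14 (-0.29, adjusted p = 0.0678). Endothelium (2 higher and 2 lower of 9, 0.05, adjusted p = 0.854), podocytes (2 and 1 of 9, 0.24, adjusted p = 0.595), neutrophils (2 higher of 5, 0.34, adjusted p = 0.0804) and red blood cells (0 of 6, 0.59, adjusted p = 0.812) did not pass. Autophagy had 3 higher and 7 lower of 18 (-0.15, adjusted p = 0.179). Oxidative stress genes had 2 higher and 2 lower of 12 (0.08, adjusted p = 0.812), with Mt2 at 334 ± 41.5 against 121 ± 59.5 (1.59). Skeletal muscle had 1 higher and 1 lower of 2 (median -0.18, while its test pointed up, adjusted p = 0.854). The adrenal gland list could not be tested.

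Across all kidney genes at 24 weeks, limma called 7150 (3760 higher, 3390 lower), of which 3674 changed at least 1.5-fold. Higher genes were 52.6% of the calls, and 40.4% under quantile normalization.

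At 30 weeks 3 mutant and 3 wild type kidneys were compared, to see whether the difference goes on. The collagen genes Col1a1 (56.3 ± 2.90 against 0.692 ± 0.259 FPKM, 5.09, adjusted p = 5.38e-07), Col1a2 (74.0 ± 7.59 against 3.13 ± 0.480, 4.19, adjusted p = 1.14e-11) and Col15a1 (125 ± 17.2 against 7.70 ± 1.51, 3.86, adjusted p = 1.73e-08) rose in 3 of 3 mutants. Fibronectin Fn1 (43.5 ± 4.67 against 1.41 ± 0.214, 4.21, adjusted p = 2.83e-06), Lcn2 (91.6 ± 10.1 against 3.37 ± 0.909, 4.42, adjusted p = 1.5e-14) and the immediate early gene Egr1 (90.1 ± 21.5 against 3.49 ± 3.71, 4.69, adjusted p = 3.91e-05) rose likewise. Wfdc15b fell to 123 ± 15.6 from 1868 ± 858 (-3.81, adjusted p = 8.08e-12), the amino acid transporter Slc7a12 to 10.1 ± 4.46 from 157 ± 60.7 (-3.83, adjusted p = 0.00357) and Hpd to 16.9 from 209 (-3.40). The mitochondrial ribosomal RNA mt-Rnr2 fell (4.02 ± 3.73 against 88.5 ± 31.7, -4.56, adjusted p = 0.0128), but not without mutant replicate 1 (-3.63, adjusted p = 0.08). The steroid enzymes Akr1c18 (-3.39) and Rdh7 (-3.34) fell, and without wild type replicate 2 neither passed (-2.93, adjusted p = 0.0699, and -2.49, adjusted p = 0.0615).

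In these kidneys 18 of 33 lists differed with the preset correlation, and 0 held with an estimated correlation. The highest medians were those of extracellular matrix (2.63, 31 of 32 higher), macrophage (2.04, 19 of 22), complement (1.91, 8 of 10) and chemokine genes (1.62, 18 of 22). Their adjusted p values ran from 8.23e-16 for the matrix to 4.65e-06 for complement, and each became adjusted p = 0.117 with an estimated correlation. The proteasome was lower in 19 of 24 (-1.60, adjusted p = 1.33e-07 and 0.331 with an estimated correlation). Oxidative phosphorylation was lower in 18 of 20 and higher in 1 (-1.46, adjusted p = 3.55e-08 and 0.280 with an estimated correlation). The proximal tubule was lower as deposited (-0.94, adjusted p = 0.00188 and 0.280 with an estimated correlation) and flipped to 0.20 under quantile normalization. The same flip took endoplasmic reticulum chaperones from -0.24 (adjusted p = 0.0422 and 0.488 with an estimated correlation) to 0.05.

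Thick ascending limb genes did not differ as a list in kidneys of 30 weeks (1 higher and 8 lower, -0.10, adjusted p = 0.0936; 0.11 under quantile normalization). The degradation genes of the endoplasmic reticulum had a median of 0.18 but a mean of -0.16. For skeletal muscle the median was -0.37 while fry pointed up. Limma called 9091 genes (4793 higher, 4298 lower), and 7960 changed at least 1.5-fold. Against 24-week wild types, unmatched in age and sex, 5238 were called. Differences were smaller for Col1a1 (3.3), Col1a2 (2.82), Col15a1 (2.56), Fn1 (2.76), Egr1 (3.63) and Wfdc15b (-2.06) but not Lcn2 (4.63). Neither mt-Rnr2 (-0.02) nor Rdh7 (-1.12) passed. The 30-week wild types have low long-minus-short values, so part of these differences follows gene length.

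The interaction asks which kidney genes differ more, or less, at 24 than at 6 weeks. Lcn2 gained a further 3.86 (adjusted p = 1.63e-14), Cfd 3.66 (adjusted p = 0.0102), Mmp7 3.57 (adjusted p = 2.15e-11), Igkv5-39 3.48 (adjusted p = 0.000298) and Ighv6-3 3.34 (adjusted p = 0.000862). Dnase1 (-2.10, adjusted p = 0.000166), the clock output gene Dbp (-2.05, adjusted p = 0.000167) and the adhesion receptor Gpr112 (-1.86, adjusted p = 2.1e-07) moved down. Slc22a22 (-1.98, adjusted p = 0.0303) did so too, but lost its call without mutant 24-week replicates 5 (-1.86), 6 (-1.87) or 1 (-1.76), mutant 6-week replicate 8 (-1.80), or wild type 6-week replicates 6 (-1.86), 2 (-1.81) or 3 (-1.78).

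Of 20 kidney lists called in the interaction, 4 held with an estimated correlation. They were macrophage genes (22 of 22 up, median 1.62, adjusted p = 4.06e-19), tubular injury genes (20 of 26, 1.05, adjusted p = 1.28e-14), NF-kB targets (14 up and 1 down, 0.95, adjusted p = 7.18e-09) and complement (8 of 10, 1.14, adjusted p = 2.76e-07). The thick ascending limb had 1 up and 7 down (-0.30, adjusted p = 0.0214 and 0.281 with an estimated correlation). Quantile normalization left it a median of -0.06 and turned its test upward. Of all genes, 3987 had a significant interaction (2384 up, 1603 down). The median gene moved by -0.11 under quantile normalization, and the share moving up went from 59.8% to 42.8%.

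Ageing was taken from wild type kidneys, 11 at 24 weeks against 7 at 6 weeks, to see what changes without the mutation. Igj, the joining chain of plasma cell antibodies, rose to 13.2 ± 10.2 from 0.897 ± 0.684 FPKM (2.54, adjusted p = 0.00383). Cyp2d12 rose to 102 ± 41.8 from 19.6 ± 3.80 (2.23, adjusted p = 3.09e-06) and the retinal dehydrogenase Aldh1a1 to 14.5 ± 6.58 from 3.17 ± 0.637 (1.81, adjusted p = 7.93e-07). Cish, an inhibitor of cytokine signals, fell to 8.20 ± 5.43 from 24.9 ± 9.40 (-1.64, adjusted p = 0.0118), but not without wild type 6-week replicate 2 (-1.51, adjusted p = 0.0578). Without that replicate Gadd45g (-1.62) and the collagen-like Emid2 (-0.99) also lost their calls (-1.45, adjusted p = 0.0723, and -0.92, adjusted p = 0.0633), and Gadd45g did so without 6-week replicate 3 (-1.44).

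The collagen gene Col3a1 fell with age (8.76 ± 4.63 against 18.0 ± 5.74, -1.04, adjusted p = 0.0273). It was lost without 24-week replicates 11 (-0.95) or 3 (-0.95) or 6-week replicates 6 (-0.98), 2 (-0.95), 4 (-0.99) or 7 (-1.01). In the kidney ageing comparison 2 of 11 lists held with an estimated correlation. Endoplasmic reticulum chaperones had 3 of 25 higher and 13 when adjusted over the list alone (median 0.28, adjusted p = 5.2e-17). Proliferation had 0 of 21 changed and 13 lower when adjusted over the list alone (-0.35, adjusted p = 3.72e-15). In all, 62 genes changed (30 higher, 32 lower; 1148 at an unadjusted p below 0.05). There were 40 without 6-week replicate 6 and 34 without 6-week replicate 2.

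**Figure D3:**
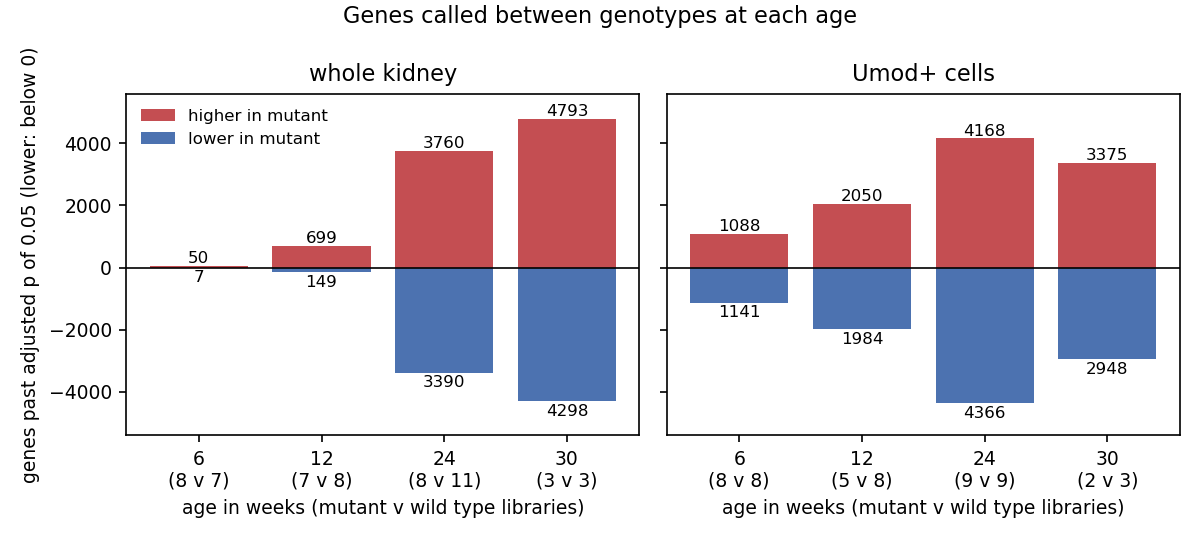
Number of genes called higher (bars above 0) or lower (below 0) in mutant than in wild type mice (vertical axis) at each age in weeks, in whole kidney and in Umod+ cells. Calls are few in kidney at 6 weeks and most numerous at 30 weeks in kidney and at 24 weeks in Umod+ cells.

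In Umod+ cells the 6-week comparison asks what the mutation does in the cells that make the protein. Asparagine synthetase Asns (chromosome 6, 7675112 to 7693254), a target of ATF4, rose to 28.7 ± 5.90 FPKM in 8 mutants from 4.04 ± 1.38 in 8 wild types (2.58, adjusted p = 2.57e-15, 8 of 8). The glutathione-degrading Chac1 rose to 14.4 ± 6.16 from 1.72 ± 0.563 (2.42, adjusted p = 2.82e-12) and the folate enzyme Mthfd2 to 26.4 ± 6.71 from 4.77 ± 1.10 (2.23, adjusted p = 2.06e-15). Arhgap36 (9.94 ± 2.54 against 0.338 ± 0.535, 3.07, adjusted p = 2.57e-15), the cornified envelope gene Sprr1a (27.0 ± 24.1 against 3.65 ± 1.76, 2.38) and Lcn2 (127 ± 31.5 against 25.2 ± 11.6, 2.34, adjusted p = 2.34e-11) rose in 8 of 8 mutants. Egf fell to 2977 ± 196 from 6416 ± 366 (-1.11, adjusted p = 5.19e-07), and so did Adamtsl2 (12.0 ± 4.87 against 27.6 ± 6.22, -1.21) and the growth factor Igf1 (9.27 ± 2.39 against 20.8 ± 4.49, -1.10, adjusted p = 0.00021).

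Among 32 lists, 16 differed in Umod+ cells at 6 weeks and 4 held with an estimated correlation. The integrated stress response rose in 23 of 34 genes (median 0.50, adjusted p = 7.39e-27; 25 when adjusted over the list alone), including Atf5 (45.4 against 10.5, 1.99), Trib3 (1.97) and Nupr1 (1.60). Tubular injury genes rose in 16 of 25 (0.49, adjusted p = 2.62e-10), chemokines in 9 of 23 (0.31, adjusted p = 4.4e-08), with Cxcl16 at 1.01. Apoptosis genes rose in 9 of 26 with 1 lower (0.14, adjusted p = 0.000342), with Casp12 (1.52). Oxidative phosphorylation fell in 18 of 20 (-0.33, adjusted p = 3.85e-17 and 0.0873 with an estimated correlation), with the succinate dehydrogenase subunit Sdha at 1315 against 1770 (-0.43). Cholesterol synthesis rose in 10 of 17 (0.37, adjusted p = 5.65e-08 and 0.177 with an estimated correlation), with Idi1 (0.52) and Hmgcs1 (0.37). In the thick ascending limb list 8 of 27 genes fell (-0.15, adjusted p = 0.00349 and 0.531 with an estimated correlation; 2 higher and 9 lower when adjusted over the list alone). Endoplasmic reticulum chaperones rose in 6 of 25 and fell in 1 (0.20, adjusted p = 0.00145 and 0.531 with an estimated correlation), while Herpud1 of the degradation list rose (414 against 270, 0.60).

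Extracellular matrix genes rose in 13 of 32 in Umod+ cells at 6 weeks and fell in 1 (0.37, adjusted p = 7.24e-07 and 0.256 with an estimated correlation), with Fn1 at 0.82 and Col4a1 at 0.56. Proximal tubule genes had a median of 0.92 with 0 of 25 changed (adjusted p = 0.000496 and 0.609 with an estimated correlation). Fatty acid oxidation had 1 higher and 7 lower, with a median of -0.16 but a mean of 0.15 (adjusted p = 0.00929 and 0.531 with an estimated correlation). In total limma called 2229 of 14775 genes (1088 higher, 1141 lower), and 381 changed at least 1.5-fold.

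At 12 weeks the Umod+ cells of 5 mutants and 8 wild types show whether these differences last. Lcn2 rose to 607 ± 303 from 20.7 ± 6.51 FPKM (4.74, adjusted p = 1.94e-20) and the pseudokinase Trib3, induced by ATF4, to 26.1 ± 7.74 from 0.524 ± 0.378 (4.15, adjusted p = 1.94e-20). Arhgap36 (16.4 ± 7.46 against 0.227 ± 0.445, 3.76), Sprr1a (51.8 ± 27.0 against 3.50 ± 1.66, 3.51), Serpina3n (11.2 ± 5.64 against 0.0998 ± 0.0759, 3.35) and Serpina10 (28.4 ± 7.78 against 2.10 ± 0.532, 3.23, adjusted p = 3.25e-20) rose in 5 of 5 mutants. Egf fell to 1502 ± 430 from 6728 ± 543 (-2.21, adjusted p = 3.4e-14). The steroid enzyme Hsd17b14 (29.3 ± 9.46 against 83.1 ± 11.4, -1.52), the morphogen Bmp4 (17.0 ± 1.4 against 49.3 ± 7.47, -1.47, adjusted p = 6.68e-14) and the phosphatase Dusp9 (-1.42) fell too.

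Of 32 lists, 20 differed in Umod+ cells at 12 weeks, and 9 held with an estimated correlation. Genes of the integrated stress response rose in 29 of 34 (0.86, adjusted p = 1.4e-28), with Atf5 at 2.88. Tubular injury genes (21 of 25, 1.27, adjusted p = 2.1e-23), extracellular matrix (28 and 1 lower, 0.94, adjusted p = 7.27e-22), chemokines (16, 0.75, adjusted p = 8.28e-11), complement (7 of 8, 0.96, adjusted p = 5.08e-07), NF-kB targets (11 and 1 lower, 0.60, adjusted p = 2.84e-07) and apoptosis (14 and 1 lower, 0.32, adjusted p = 1.16e-05) rose. Thick ascending limb genes fell in 18 of 27 (-0.56, adjusted p = 4.96e-11; 19 when adjusted over the list alone) and fatty acid oxidation in 11 of 17 (-0.42, adjusted p = 7.31e-09). Oxidative phosphorylation fell in 18 of 20 (-0.45, adjusted p = 3.21e-14 and 0.0957 with an estimated correlation).

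Lists of other cell types were higher in mutant Umod+ cells at 12 weeks, each with the preset correlation only. Macrophage genes rose in 15 of 22 (1.07, adjusted p = 1.58e-09 and 0.127 with an estimated correlation) and podocyte genes in 9 of 9 (0.80, adjusted p = 3.37e-05 and 0.0987 with an estimated correlation). The cholesterol list no longer differed (median -0.01, mean 0.01). Altogether limma called 4034 genes (2050 higher, 1984 lower).

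At 24 weeks 9 mutants and 9 wild types give the largest comparison of Umod+ cells. Lcn2 reached 877 ± 174 against 26.8 ± 8.37 FPKM (5.03, adjusted p = 7.47e-25, 9 of 9 mutants). Mmp7 (23.8 ± 7.49 against 0.259 ± 0.332, 4.28; chromosome 9, 7628230 to 7699585), Igfbp2 (39.1 ± 27.4 against 1.10 ± 0.880, 4.16) and Fgg, a fibrinogen chain, (22.0 ± 4.31 against 0.708 ± 0.538, 3.79) rose. The keratin gene Krt19 (47.5 ± 14.7 against 2.12 ± 0.758, 3.93, adjusted p = 2.63e-23), the calcium binding S100a6 (218 ± 50.0 against 14.7 ± 3.07, 3.79, adjusted p = 7.47e-25) rose too. So did the envelope genes Sprr2g (20.7 ± 10.6 against 0.129 ± 0.195, 4.11) and Sprr1a (60.0 ± 24.0 against 3.39 ± 2.43, 3.88), with Arhgap36 (18.6 ± 7.16 against 0.268 ± 0.228, 3.88). Genes of antigen-presenting and myeloid cells were among the largest gains: H2-Aa (134 ± 85.4 against 6.94 ± 4.85, 4.12, adjusted p = 1.29e-15), H2-Ab1 (102.5 ± 68.7 against 6.34 ± 4.21, 3.86) and Lyz2 (59.5 ± 36.9 against 2.23 ± 0.893, 4.08).

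Egf (chromosome 3, 129673842 to 129755388) had the largest fall in Umod+ cells at 24 weeks, from 6508 ± 1030 to 685 ± 302 (-3.34, adjusted p = 2.31e-24, 9 of 9). The potassium channel Kcnt1 (2.29 ± 1.08 against 17.7 ± 8.0, -2.46), Pex5l (1.59 ± 0.517 against 11.6 ± 1.81, -2.29, adjusted p = 1.1e-20), the long noncoding RNA Neat1 (41.9 ± 19.0 against 282 ± 285, -2.26, adjusted p = 1.43e-06) and Lrrc66 (29.3 ± 10.2 against 132 ± 16.2, -2.19) fell. Lipoprotein lipase Lpl (117 ± 37.4 against 472 ± 45.5, -2.06, adjusted p = 8.59e-19), Adssl1 (10.1 ± 2.87 against 44.4 ± 3.83, -2.07), Tmem86a (-2.10), Sycn (-2.08), Phyhip (-2.01), Robo3 (-1.98) and Lrrc52 (-1.92) fell as well.

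By list, 22 of 32 differed in Umod+ cells of 24 weeks and 8 held with an estimated correlation. Thick ascending limb genes fell in 25 of 27 (median -0.81, adjusted p = 1.02e-12; 26 when adjusted over the list alone). Examples are Kng2 (691 ± 107 against 1396 ± 132, -1.02), Tmem207 (50.2 ± 17.8 against 167 ± 17.5, -1.77) and the nuclear receptor Esrrb (30.6 ± 6.14 against 77.1 ± 7.18, -1.32). The integrated stress response rose in 28 of 34 and fell in 1 (0.88, adjusted p = 2.19e-11), with Atf5 at 64.4 ± 16.5 against 10.6 ± 1.16 (2.46), Nupr1 at 151 ± 25.5 against 23.3 ± 6.92 (2.68), Trib3 at 15.0 ± 7.43 against 0.649 ± 0.317 (3.17) and Aldh1l2 (2.28). Apoptosis genes rose in 17 of 26 and fell in 2 (0.52, adjusted p = 5.05e-05), led by Casp12 (16.2 ± 2.69 against 0.619 ± 0.312, 3.41, adjusted p = 9.54e-27), Casp4 (2.92) and Pmaip1 (2.80). Tubular injury genes rose in 23 of 25 and fell in 1 (1.80, adjusted p = 9.05e-17). Extracellular matrix rose in 30 of 32 with 1 lower (1.72, adjusted p = 1.75e-19), with Fn1 (12.9 ± 3.17 against 0.949 ± 0.228, 2.80), Col4a1 (59.4 ± 9.31 against 14.6 ± 2.53, 1.95) and Tnc (1.67). Chemokines rose in 22 of 23 (1.57, adjusted p = 4.82e-13), with Cxcl16 (72.8 ± 9.52 against 25.0 ± 2.09, 1.5), Tnf (1.98) and Cxcl2 (2.90). Complement rose in 8 of 8 (1.87, adjusted p = 4.29e-07), with C3 (36.5 ± 10.6 against 2.13 ± 1.13, 3.62) and Serping1 (3.10). Macrophage genes rose in 22 of 22 (2.27, adjusted p = 1.66e-17), with Ctss (28.8 ± 15.7 against 1.12 ± 0.612, 3.73), C1qc (3.19) and Lgals3 (553 ± 108 against 148 ± 17.9, 1.88).

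Genes of other cell types rose in mutant Umod+ cells at 24 weeks, in lists called with the preset correlation only. Principal cell genes rose in 8 of 9 (1.41, adjusted p = 0.000235 and 0.160 with an estimated correlation), with the sodium channel Scnn1b at 74.9 ± 23.6 against 13.9 ± 2.71 (2.31) and Hsd11b2 at 325 ± 113 against 60.9 ± 10.3 (2.33). Intercalated cell genes rose in 11 of 14 and fell in 1 (1.47, adjusted p = 2.8e-05 and 0.154 with an estimated correlation), with the proton pump gene Atp6v0d2 (62.9 ± 10.1 against 14.3 ± 3.33, 2.08) and its regulator Foxi1 (32.5 ± 13.0 against 6.16 ± 1.59, 2.18). Endothelium (9 of 10, 1.49, adjusted p = 2.09e-06 and 0.0714 with an estimated correlation) rose, with Emcn at 70.8 ± 13.1 against 18.8 ± 4.53 (1.87). Podocyte genes rose in 8 of 9 (0.88, adjusted p = 0.00141 and 0.160 with an estimated correlation). Fibroblasts rose in 10 of 12 (1.00, adjusted p = 2.67e-05 and 0.122 with an estimated correlation), with Dcn at 12.1 ± 3.71 against 0.579 ± 0.253 (3.01). Lymphocyte genes rose in 13 of 13 (0.98, adjusted p = 1.41e-06 and 0.0766 with an estimated correlation), with Lck (1.78). Neutrophil genes rose in 3 of 3 (1.60) and red cell genes in 5 of 5 (1.77), among them Hbb-b1 (85.1 ± 111 against 13.9 ± 12.1, 2.36), but these lists did not differ from other genes (adjusted p = 0.071 and 0.131). The proximal tubule had 4 of 25 higher (0.85, adjusted p = 0.145; 1 when adjusted over the list alone), with Aqp1 at 177 against 80.1 (1.14).

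Interferon genes rose in 20 of 21 in these cells (1.42, adjusted p = 1.03e-09 and 0.0645 with an estimated correlation), with Rtp4 (1.83). NF-kB targets rose in 11 with 1 lower (1.33, adjusted p = 3.04e-05 and 0.0673 with an estimated correlation), with Icam1 at 45.0 ± 15.0 against 4.29 ± 1.11 (3.07). Targets of p53 rose in 9 and fell in 3 of 14 (0.63, adjusted p = 0.0135 and 0.160 with an estimated correlation): Cdkn1a rose (67.9 ± 15.2 against 9.34 ± 2.93, 2.75) with Cdkn2a (1.13), and Sesn1 fell (-0.81). Proliferation genes rose in 17 of 20 (0.63, adjusted p = 5.05e-05 and 0.160 with an estimated correlation). Oxidative stress genes rose in 8 of 12 (0.34, adjusted p = 0.0138 and 0.130 with an estimated correlation), with the heme oxygenase Hmox1 at 39.3 ± 11.2 against 9.29 ± 4.37 (2.02). Immediate early genes, which dissociation of tissue also induces, rose in 16 of 19 (0.93, adjusted p = 0.000166 and 0.368 with an estimated correlation), with Klf4 (2.07) and Myc (2.01). Oxidative phosphorylation fell in 20 of 20 (-0.68, adjusted p = 5.97e-13 and 0.0891 with an estimated correlation), with Sdha at 925 ± 105 against 1744 ± 125 (-0.92). Fatty acid oxidation fell in 12 of 17 with 1 higher (-0.61, adjusted p = 5.07e-06 and 0.0887 with an estimated correlation), with Hadhb at 333.5 ± 39.0 against 678 ± 40.6 (-1.03).

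The other lists did not differ from other genes in Umod+ cells at 24 weeks. Endoplasmic reticulum chaperones had 2 higher and 7 lower of 25 (-0.03, adjusted p = 0.407) and the degradation genes 2 and 7 (-0.07, adjusted p = 0.278), with Herpud1 now lower (187 ± 22.5 against 254 ± 44.0, -0.42). Distal convoluted tubule genes had 1 higher and 6 lower of 9 (-0.76, adjusted p = 0.145): the calcium channel Trpv5 rose (24.1 ± 8.81 against 1.79 ± 0.641, 3.12), while Kl (80.9 ± 12.4 against 203 ± 23.6, -1.32) and Klhl3 (-1.79) fell. Autophagy had 5 higher and 5 lower of 17 (-0.07, adjusted p = 0.629), with the cargo receptor Sqstm1 higher (897 ± 93.5 against 407 ± 17.9, 1.13) and Gabarapl1 lower (772 ± 105 against 1756 ± 185, -1.19). The proteasome (6 higher, 3 lower, 0.03, adjusted p = 0.607), cholesterol synthesis (1 and 3, -0.07, adjusted p = 0.628) and skeletal muscle (1 of 2 higher, 0.21, adjusted p = 0.361) did not differ either. In all limma called 8534 genes (4168 higher, 4366 lower), and 3429 changed at least 1.5-fold. The count was 3512 with a macrophage covariate and 5512 with a mean of at least 5 FPKM. The sex balance differs between these groups.

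At 30 weeks the Umod+ cells of 2 mutants and 3 wild types extend the series. Krt19 rose to 166 ± 2.57 from 4.65 ± 0.943 FPKM (4.90, adjusted p = 4.19e-15), the GABA receptor subunit Gabrp to 36.0 ± 3.91 from 0.535 ± 0.306 (4.61) and Igfbp2 to 65.4 ± 1.43 from 1.89 ± 0.562 (4.54). Sprr2f (4.52) and the matrix gene Ltbp2 (4.52) rose, each in 2 of 2 mutants. Nccrp1 fell to 13.5 ± 0.315 from 225 ± 36.9 (-3.95, adjusted p = 4.03e-13), Egf to 461 ± 0.0573 from 5249 ± 287 (-3.50, adjusted p = 4.86e-14) and Tmem207 to 19.4 ± 0.906 from 142 ± 20.1 (-2.80), with Sycn (-3.66), Tmem86a (-3.07) and Kcnt1 (-2.69).

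Of 32 lists, 23 differed in Umod+ cells at 30 weeks, and 11 held with an estimated correlation. Extracellular matrix (30 of 32, 2.57, adjusted p = 4.17e-26), tubular injury (23 of 25, 1.85, adjusted p = 6.91e-15), chemokine (21 of 23, 2.02, adjusted p = 7.06e-12) and interferon genes (20 of 21, 1.63, adjusted p = 9.71e-11) were higher. So were endothelium (9 of 10, 2.02, adjusted p = 5.23e-08), NF-kB targets (12 and 1 lower, 1.57, adjusted p = 1.12e-06), complement (8 of 8, 2.33, adjusted p = 5.04e-06) and apoptosis genes (17 and 1 lower, 0.66, adjusted p = 3.31e-05). Thick ascending limb genes (23 of 27, -0.92, adjusted p = 2.41e-11), oxidative phosphorylation (20 of 20, -1.09, adjusted p = 1.06e-17) and fatty acid oxidation (14 of 17, -1.02, adjusted p = 4.51e-10) were lower. The integrated stress response did not hold (23 higher and 1 lower, 0.76, adjusted p = 3.31e-05 and 0.0553 with an estimated correlation), nor did macrophage genes (21 higher, 2.39, adjusted p = 3.26e-11 and 0.0838 with an estimated correlation). The proteasome was lower in 11 members (-0.24, adjusted p = 0.00611 and 0.507 with an estimated correlation) and flipped to 0.01 under quantile normalization. Oxidative stress genes had a median of -0.16 but a mean of 0.08. In total limma called 6323 genes (3375 higher, 2948 lower).

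For the interaction in Umod+ cells, the gain from 6 to 24 weeks was largest in Mmp7 (3.55, adjusted p = 1.65e-12), Sprr2g (3.48), Sprr2f (3.47), the complement gene C1qa (3.46, adjusted p = 4.81e-12) and Lyz2 (3.39). Neat1 (-2.48, adjusted p = 0.000305), Kcnt1 (-2.26), Egf (-2.23, adjusted p = 8.57e-12), Pdzd9 (-2.0) and Lrrc66 (-1.89) moved down. Of the 23 lists called, 9 held with an estimated correlation. In the thick ascending limb 23 of 27 genes moved down (median -0.67, adjusted p = 2.12e-12). Macrophage (22 up, 2.08, adjusted p = 2.7e-19), tubular injury (20 up, 1.53), endothelium (9 up, 1.52), extracellular matrix (29 up and 1 down, 1.4) and complement genes (8 up, 1.33) moved up. Interferon (20 up, 1.27), chemokine (18 up, 1.0) and apoptosis genes (12 up and 2 down, 0.29, adjusted p = 0.00155) did so as well. The stress response list, already higher at 6 weeks, moved up by a median of 0.15 (13 up and 3 down, adjusted p = 0.0235 and 0.305 with an estimated correlation). Altogether 5513 genes had a significant interaction (2854 up, 2659 down).

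Ageing of wild type Umod+ cells, 9 mice at 24 weeks against 8 at 6 weeks, asks what changes in these cells without the mutation. It raised Tmem28 (5.22 ± 0.545 against 1.47 ± 0.427 FPKM, 1.34, adjusted p = 6.62e-15), the antibody transporter Pigr (80.3 ± 28.5 against 33.3 ± 10.9, 1.22) and Malat1 (22.5 against 8.92, 1.10). Cd36 (1.07) and Cpeb1 (1.02) rose too. The glucose transporter Slc5a10 of the proximal tubule fell (3.65 ± 3.43 against 12.9 ± 6.58, -1.68, adjusted p = 0.00314). No list held with an estimated correlation, and 13 of 32 were called without it. Principal cells were lower in 6 of 9 (-0.75, adjusted p = 1.03e-07 and 0.317 with an estimated correlation) and intercalated cells in 7 of 14 (-0.55, adjusted p = 9.62e-08 and 0.317 with an estimated correlation). The proximal tubule had 0 of 25 changed and 13 lower when adjusted over the list alone (-1.12, adjusted p = 1.34e-07 and 0.628 with an estimated correlation). In all 1047 genes changed (543 higher, 504 lower), with 637 without 6-week replicate 1 and 321 lower genes without 24-week replicate 1. Higher genes were 51.9% of the calls, and 68.3% under quantile normalization.

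Comparing tissues asks whether the same genes differ in whole kidney and in Umod+ cells, over the 13195 genes tested in both. At 6 weeks 28 genes were higher in each against 3.48 expected, and 0 were lower in each against 0.237. At 12 weeks 355 higher (75.4 expected) and 70 lower (17.2) were shared, at 24 weeks 1940 (846) and 1588 (892), and at 30 weeks 2029 (947) and 1646 (785). Of 4057 genes called in each tissue at 24 weeks, 3528 (87.0%) had the same sign, and the correlation of the log2 differences over all genes was 0.52. Only 1 mouse of 24 weeks gave a library in each tissue, but 15 mice of 6 weeks, 12 of 12 weeks and 5 of 30 weeks did. The expected counts take the lists as independent, so at those ages sharing of mice can add to the overlap.

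Comparing ages asks whether genes that differ early still differ later in other mice. In whole kidney 49 of 50 genes higher at 6 weeks were higher at 12 weeks (2.14 expected) and 50 of 50 at 24 weeks (11.5). Of the 7 lower genes 2 recurred at 12 weeks (0.0638 expected) and 3 at 24 weeks (1.45). From 12 to 24 weeks 686 of 699 higher genes (161 expected) and 123 of 149 lower genes (30.9) recurred, and from 24 to 30 weeks 2557 higher (1100) and 2132 lower (891). In Umod+ cells 497 of 1088 higher genes (151 expected) and 655 of 1141 lower genes (153) of 6 weeks recurred at 12 weeks, and 1873 of 2050 (578) and 1821 of 1984 (586) of 12 weeks at 24 weeks.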

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

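The tests of explanations below were chosen after the results had been seen, and those marked so were predicted before their own values were known. Comparisons with other splits of the mice were planned before the data were examined. Among 110 groups of 4 to 10 libraries or gene values, 9 had a library standing apart, and chance flags about 1 in 20 groups. In Umod+ cells, mutant 24-week replicate 8 had a long-minus-short value of -0.38, 798416 FPKM in named genes and 70.7% in unnamed loci, and wild type 12-week replicate 2 had 69.1% in unnamed loci. In whole kidney, unnamed loci took 32.1% of mutant 24-week replicate 1, 48.5% of mutant 6-week replicate 1 and 46.0% of wild type 12-week replicate 4. Umod stood at 11.85 on the log2 scale in mutant 12-week kidney replicate 7, and Igfbp2 at 6.77 in mutant 24-week cell replicate 5.

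Genes and lists whose difference changed between 6 and 24 weeks, by the interaction test, numbered 3987 genes in kidney and 5513 in Umod+ cells. In kidney these were Lcn2 3.86, Cfd 3.66, Mmp7 3.57, Igkv5-39 3.48, Ighv6-3 3.34, Dnase1 -2.1, Dbp -2.05, Slc22a22 -1.98, Gpr112 -1.86 and Umod -0.54, and the macrophage 1.62, tubular injury 1.05, NF-kB 0.95 and complement 1.14 lists. In the cells they were Mmp7 3.55, Sprr2g 3.48, Sprr2f 3.47, C1qa 3.46, Lyz2 3.39, Neat1 -2.48, Kcnt1 -2.26, Egf -2.23, Pdzd9 -2.0 and Lrrc66 -1.89. Cell lists were thick ascending limb -0.67, endothelium 1.52, macrophage 2.08, apoptosis 0.29, tubular injury 1.53, extracellular matrix 1.4, chemokines 1.0, interferon 1.27 and complement 1.33. Loci without a gene name, outside the comparisons, differed at 24 weeks in 725 of 6871 in kidney (380 higher, 345 lower) and 843 of 3517 in cells (224 higher, 619 lower).

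For other splits of the same mice, chance can be excluded in kidney at 6 weeks (57 genes, highest other split 15; 99 and 18 with the sex covariate), at 24 weeks (7150 and 1570), for the interaction (3987 and 1900) and for ageing (62 and 4; 225 and 10 with the sex covariate). In each of these 1 of 100 splits, the real one, called as many genes. The same holds in Umod+ cells at 6 weeks (2229 and 448), 12 weeks (4034 and 1648), 24 weeks (8534 and 4052), for the interaction (5513 and 1119) and for ageing (1047, with every other split lower). In kidney at 12 weeks the splits without a covariate cannot exclude chance, with 848 genes against 4832 in the highest other split and 5 of 100 as large. That split points to a structure of the mice: its groups differ by 5.5 in sex score (-0.72 in the real split) and by 0.64 in long-minus-short value (0.12). With the sex covariate 1754 genes stood against 2185, whose groups differ by -0.62 in long-minus-short value. With 2 of 100 as large, chance stays possible. The groups of the cell split that called 4052 genes differ by 3.46 in sex score. In kidney at 30 weeks there are too few splits: 9091 genes against 3, 1 of 10. The 2 against 3 cell libraries at 30 weeks were not split.

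More genes were called in kidney at 30 than at 24 weeks, although there were fewer mice. Length bias of the wild type 30-week libraries is not the whole cause, since removing each library's trend on gene length left 8180 calls at 30 weeks against 6965 at 24. Mutants differed between 24 and 30 weeks in 888 genes and wild types in 7137, so mutant progression is not the whole cause. These predictions were written before their values but after it was known that with a length covariate fewer genes were called at 30 than at 24 weeks. Some mutant progression, the 3 wild type mice, their handling and ageing stay open.

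Genes of other cell types rose in mutant Umod+ cells at 24 weeks. A lower share of Umod+ cells among the isolated cells would, if all other cell types were carried over alike, raise them by a like part of their kidney level, but the lower quartile of intercalated cells was 0.404 against an upper quartile of 0.0987 in the proximal tubule, a prediction written after the list values were known. Carry-over of immune cells would make 3 antigen-presentation genes follow 19 other macrophage genes across the 9 mutants, and they did (r = 0.99, exact p = 1.1e-05; rank correlation 0.98, exact p = 4.96e-05; 0.98 and exact p = 0.000794 without the 2 farthest mice). This is consistent with carry-over (r = 0.99), and expression by the cells themselves was not tested. Carry-over that differs between cell types and a gain of collecting duct genes in the mutant cells stay open.

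Thick ascending limb genes were lower in mutant Umod+ cells at 24 weeks, with a list median of -0.81. Fewer such cells with unchanged levels in each would leave the isolated cells alike, yet of the 9 members lower in whole kidney the 7 measured in the cells had a median of -1.07 and an upper quartile of -0.88. Dilution by other cells would lower all members alike, and 8 lay more than 3 standard errors below the median: Egf, Tmem207, Esrrb, Wnk4, Casr, Ppp1r1a, Foxq1 and Slc12a1. The predictions for these were written after the list values were known. Lower levels of these genes per cell stay open.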

How the results depend on the processing

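The settings were fixed before the data were examined, except those said here to be added after seeing the data. The cause was not tested for any change below, except that the stricter filter tests fewer genes (10082 in kidney) and leaving libraries out leaves fewer mice. No paired analysis was possible because each comparison sets different mice of 1 tissue against each other and the replicate numbers only name samples; the 33 mice shared by the tissues, which were never tested against each other, link no mutant to a wild type. Sign changes of values that passed under neither setting were not counted as reversals (269 gene, 126 list and 12 Umod values). Of 18353 gene values 13 reversed, 65 newly passed, 467 no longer passed and 17808 kept their call. Of 4068 list values 6 reversed, 84 newly passed, 228 no longer passed (150 of them with an estimated correlation) and 3750 kept their call. Of 1146 counts 124 moved by more than 1.5 times, and 7 of 32 overlaps did with an adjusted p below 0.1.

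With a mean of at least 5 FPKM the counts were 35, 337 and 4393 in kidney at 6, 12 and 24 weeks, 2323 for its interaction and 32 for its ageing, and 5512 in cells at 24 weeks and 3591 for their interaction. A fold of at least 1.5 gave 453 and 3674 in kidney at 12 and 24 weeks and 37 for ageing, and 381, 1251 and 3429 in cells at 6, 12 and 24 weeks, 2597 for the interaction and 172 for ageing. Array weights gave 840 in kidney at 6 weeks, 7103 for the interaction and 733 for ageing, and 3860 in cells at 6 weeks. The sex covariate gave 99 and 1754 in kidney at 6 and 12 weeks and 225 for ageing, and the proximal tubule covariate 576 for ageing in cells.

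Under quantile normalization Umod was 0.05 in kidney at 24 weeks, -0.23 at 30 weeks and -0.03 in the interaction, and Emcn (0.02) and Ctsl (0.09) reversed at 24 weeks. At 30 weeks Atp1b1 (0.84), Calr (0.79), Herpud1 (0.18), Ctsl (0.72), Psmc1 (0.24), Atp5a1 (0.45) and Acadm (0.08) reversed, with the proximal tubule (0.2), chaperone (0.05) and oxidative stress (0.36) lists. The thick ascending limb list (-0.06) reversed in the kidney interaction and the proteasome list (0.01) in cells at 30 weeks.

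Of the settings added after seeing the data, the length covariate gave 114 and 1556 in kidney at 6 and 12 weeks, 6346 for the interaction and 300 for ageing, and 388 for ageing in cells. Without kidney libraries of low long-gene level 562 genes were called at 12 weeks. With 24-week in place of 30-week wild types (age and sex unmatched) 5238 were called and Umod was -0.99. Sgms2 (-0.67), Calb1 (-0.35), Pdia3 (-0.54) and the endothelium list (0.02) reversed. The macrophage covariate gave 3512 in cells at 24 weeks, 3020 for the interaction and 2180 for ageing.

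Leaving out each library in turn gave, in kidney, 37 to 68 genes at 6 weeks, 591 to 906 at 12, 6283 to 7510 at 24, 7408 to 8714 at 30, 3285 to 4537 for the interaction and 34 to 64 for ageing. In cells it gave 1819 to 2277, 3146 to 3983, 8280 to 8588, 4665 to 5908, 5303 to 5571 and 637 to 1246. Umod in kidney ranged from -0.04 to 0.12 at 6 weeks, -0.11 to 0.04 at 12, -0.51 to -0.45 at 24, -1.69 to -1.38 at 30, -0.6 to -0.45 for the interaction and -0.22 to -0.16 for ageing. Where 1 cell library was left in a group at 30 weeks, it was taken to vary like the other groups.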

Other observations

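The genes in this part were chosen after their values were seen, and their values are limma results at 24 weeks. Single clock genes were looked at without a test of the group. Dbp (8.66 ± 4.92 FPKM in 8 mutant kidneys against 26.3 ± 5.77 in 11 wild types, -1.63, adjusted p = 2.49e-06), Tef (-0.98), Hlf (-0.95), Per3 (-0.8, adjusted p = 0.0197) and Nr1d2 (24.5 ± 6.48 against 46.3 ± 10.5, -0.9, adjusted p = 4.04e-08) fell in kidney. Arntl (8.58 ± 2.26 against 4.00 ± 1.16, 0.94, adjusted p = 6.12e-05) and Npas2 (1.07) rose, as did Per1 (0.94, adjusted p = 0.023) and Cry1 (0.42), while Nr1d1 (-0.36, adjusted p = 0.179) and Clock (-0.17, adjusted p = 0.102) did not pass. In Umod+ cells Dbp (11.0 ± 3.96 against 28.6 ± 7.04, -1.34, adjusted p = 1.28e-05, 9 of 9 mutants), Tef (-1.15), Per3 (-0.83), Per2 (-0.35), Nr1d2 (-0.73) and Nr1d1 (-0.61) fell and Arntl (0.79) and Npas2 (0.73) rose, while Hlf (-0.19, adjusted p = 0.604), Per1, Cry1 and Clock did not pass. At 6 weeks none of these was called by limma in either tissue, and at 12 weeks Nr1d1 was, in cells (-0.46). In cells at 30 weeks Per1 rose (1.19). In kidney at 30 weeks Nr1d1 (1.94, adjusted p = 4.11e-05) and Per1 (2.59, adjusted p = 0.00039) rose and Clock fell (-0.75, adjusted p = 6.72e-05), and Dbp (0.78), Tef (0.38) and Hlf (0.78), with positive differences, did not pass. The time of collection is not given in the sources used here.

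Some single genes of calcium and phosphate transport were looked at as well, again without a test of the group. In Umod+ cells Trpv5 (3.12, adjusted p = 1.19e-19) and S100g (1178 ± 339 against 375 ± 124, 1.66, adjusted p = 3.28e-08) rose with Cyp24a1 (1.6, adjusted p = 0.000932) and Cyp27b1 (0.58, adjusted p = 0.0063), Kl fell (-1.32) and Calb1 (-0.2, adjusted p = 0.539), Slc34a1 (0.85, adjusted p = 0.123) and Slc34a3 (0.44, adjusted p = 0.436) did not pass. In kidney S100g (-0.48, adjusted p = 0.0281; 0.02 under quantile normalization) and Calb1 (-0.5, adjusted p = 0.00943; -0.09 and not passing under that scaling) fell with Kl (-1.14), and Trpv5 rose (0.38, adjusted p = 0.0399; 0.29 and not passing under that scaling). There the phosphate transporters Slc34a1 (1095 ± 416 against 2493 ± 642, -1.24, adjusted p = 6.2e-08) and Slc34a3 (24.5 ± 12.3 against 74.8 ± 7.07, -1.71, adjusted p = 3.62e-13) fell too, and Cyp24a1 (0.18) and Cyp27b1 (0.48) did not pass.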
